A study of Mus musculus with 36 samples.

How the data were processed

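RNA of WT and SIRT1-deficient (KO) mouse ES cells was measured on 36 1-colour Agilent 4x44K arrays of design 014868, 3 for each of 12 groups defined by genotype, medium and time. Per the labels' protocols, cells grew in glucose-rich medium with serum and the cytokine LIF, which holds ES cells in the undifferentiated state, with 200 µM methionine (complete) or 6 µM methionine (restricted), and RNA was isolated on columns and labelled with Cy3. Groups and replicate numbers were read from the sample labels. Per the file headers, the deposited scanner files came from Agilent Feature Extraction 12.0.0.7, whereas the submitters' processing notes name version 9.5, and which of them made the values was not settled. The authors deposited the processed signal as a linear intensity, already background-subtracted by Feature Extraction, per the file headers. The deposited table of the whole series held the same intensity values, linear and uncentred, with a largest difference of 0 from the scanner files and column medians from 42.4 to 131. Every log2 value was computed here from these intensities. The flags for spots well above background, outliers and saturation were read as the authors' files give them, as a code other than a measurement, per the file headers.

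Each array held 45018 spots, of which 43379 were not controls and carried 41174 probes. Control spots were left out. Outlier spots (75 to 478 per array) were left out too, while the 1 saturated spot was kept. The log2 processed signal was averaged over spots of a probe, and each array's 75th percentile, 691 to 1403 in linear units, was subtracted. Probes were kept if well above background on every array of at least 1 group. Names came from RefSeq accessions through a table of the GRCm38.p6 assembly, which named 28223 probes (68.5%) with 19096 symbols. The other 12951 probes kept the file's identifier and are not named in the text. The array's own build is not given in the sources used here, so no coordinates are printed, and genes are placed only by their chromosome-mates in that table. For 6862 symbols with more than 1 probe, the passing probe with the highest mean signal over all arrays was used. Probes of a gene disagreed at times, and 405 genes had probes called in both directions for restricted against complete medium in WT cells at 72 h.

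In this way 22446 genes were tested, 16160 of them with a symbol. A group-means model over all 12 groups was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with a median residual SD of 0.251 log2 units and 24 residual degrees of freedom. The 15 contrasts were KO against WT in complete medium (mean of the 3 times and each time), restricted against complete medium in each genotype at each time, the difference of these responses between genotypes at each time, and the response at 72 h minus that at 6 h in each genotype. Tests were 2-sided and p-values were adjusted by Benjamini-Hochberg within a contrast, and a gene was called at an adjusted p under 0.05. Where every array of a group was not well above background, only a bound is given as at least N-fold. The bound sets the mean of the brighter group against the mean, per array, of the higher of the lowest signal among probes well above background and the dim probe's own, and no fold is given where both groups were dim. For a mean over times or a difference of responses with some dim groups the size is uncertain, and the text says so. A count over the list alone repeats the adjustment within the measured members of a list.

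Before the data were examined, 26 gene lists were fixed, with 534 entries. They covered the methionine cycle, polyamines, serine and one-carbon enzymes, the amino acid response, aminoacyl-tRNA synthetases, naive and primed pluripotency, germ layers, trophoblast, the 2-cell-like state, fibroblast and feeder markers, p53 targets, apoptosis, cell cycle, ribosome biogenesis, cholesterol synthesis, glycolysis and hypoxia, Nrf2 and glutathione, sirtuins and NAD, chromatin and DNA methylation enzymes, imprinted genes, germline genes, interferon genes, and retinoic acid and Hox genes. Lists were tested with camera at a correlation of 0.01 between genes, adjusted over all 390 pairs of list and contrast, and again with the correlation estimated from the residuals (the second adjusted p given). Camera asks whether the members of a list shift relative to all other genes. Named genes followed a rule, also fixed in advance. It takes Sirt1 and the presets Mat2a, Myc, Nanog, Pou5f1, Sox2, Atf4, Asns, Trib3, Chac1 and Ddit3. It adds, in each comparison, the 5 highest and 5 lowest called genes with an official symbol whose arrays did not overlap between groups (for differences and means over times, with the same sign in each replicate number). It further adds up to 4 members with the smallest p of each list described. The text names part of these genes where their call did not rest on 1 array, and says so otherwise, and results of some genes under the rule are not reported here.

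The arrays lay on 12 slides and 2 scan days, with a single array, KO complete-medium 72 h replicate 1, scanned on the second. All 4 groups at 6 h shared slides 1, 2 and 3, so slide could be fitted as a fixed block for 9 contrasts. At 24 and 72 h complete and restricted medium lay on different slides, and slide entered those contrasts only as a random block (duplicateCorrelation, consensus correlation 0.0896). Groups share replicate numbers in the labels. Deviations from the group mean correlated above 0.1 for each of the 3 numbers between WT and KO in complete medium at 6 h (0.25, 0.15 and 0.14) and between media in WT at 24 h (0.19, 0.1 and 0.18). They did so too between WT and KO in restricted medium at 6 h (0.41, 0.11 and 0.41), 24 h (0.47, 0.41 and 0.39) and 72 h (0.46, 0.35 and 0.69). The pairing comes from the replicate numbers in the labels, and several of these pairs shared a slide.

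The fit and the list test were run on simulated data for 22446 genes, 200 of which were changed. For KO against WT at 6 h, 20.9, 67.2 and 80.3% of genes changed 1.5, 2 and 4-fold were called in the right direction, with 7 unchanged genes called. For the medium response in WT at 72 h the shares were 25.4, 58.2 and 87.9%, with 6 such genes. For the difference of responses at 72 h they were 11.9, 44.8 and 72.7%, with 7. In each, camera called a list shifted by 0.5 and 0 other lists. Genes were drawn independently, so lists of correlated genes were not tested. A shift of -0.3 put on 1 chromosome was recovered as -0.288, with the largest other chromosome at 0.02.

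Alternatives fixed in advance were normexp background correction (offset 50, planned on mean spot signals and run on median spot and background signals, since the files used here hold no mean signal), quantile normalization, the array median in place of the 75th percentile, the deposited table, no filter or a stricter filter on dim probes, all probes, only the groups of a contrast, other variance models for genes and lists, slide and replicate number as blocks, array weights, a 1.5-fold threshold, an estimated correlation for lists and the omission of each array in turn. Added after the data had been seen were the omission of the arrays on slides 11 and 12, the other Sirt1 probe and the omission of the genes of 2 chromosomes. With the array median as the reference, the median of all genes lay at 0.16 for KO against WT at 6 h, -0.20 and -0.26 for the medium in WT at 24 and 72 h, -0.10 and -0.21 in KO at 24 and 72 h, -0.11 and 0.11 for the difference of responses at 6 and 24 h, and -0.34 and -0.14 for 72 h minus 6 h in WT and KO. Changes are given relative to the 75th percentile, and which reference holds the total RNA constant was not analysed here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, and tables were handled with pandas 2.3.3 and numpy 2.4.6.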

Results

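Gene expression was measured in mouse embryonic stem (ES) cells, pluripotent cells of the early embryo kept in culture, on Agilent whole-genome arrays. WT cells and KO cells lacking SIRT1, an NAD-dependent protein deacetylase, were grown in complete medium with 200 µM methionine or in restricted medium with 6 µM methionine. Methionine, an essential amino acid, is the precursor of S-adenosylmethionine, the methyl donor of DNA and histone methylation. Cells were taken at 6, 24 and 72 h, which gave 12 groups of 3 arrays and 36 arrays in all. On each array between 60.6% and 77.2% of non-control spots were well above background, and the number of arrays limits the precision. Replicate arrays of a group correlated at 0.967 to 0.995 across probes and shared at most 1 identical value. Changes are log2 fold changes ± SE with 3 arrays per group, and list results come from camera with Benjamini-Hochberg adjustment. The labels do not say that the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these samples.

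The deleted gene came first, as it bears on the labels. On the tested Sirt1 probe, the KO mean lay below the WT mean in complete medium (-1.13 ± 0.25, limma adjusted p = 0.000529). The difference was -1.79 at 6 h (adjusted p = 0.00251), -1.24 at 24 h (adjusted p = 0.0375) and -0.37 at 72 h, where arrays overlapped and the test did not pass (adjusted p = 0.566). The 24 h call ended without any of 4 of the 6 arrays, and was weakest without KO complete-medium 24 h replicate 2 (-0.91, adjusted p = 0.202). A further Sirt1 probe, outside the gene-level fit, gave -2.34 (adjusted p = 2.75e-19 over all probes), with WT means of 2.53 ± 0.18, 2.69 ± 0.09 and 1.95 ± 0.12 (SD, n = 3) against KO means of 0.04 ± 0.17, 0.29 ± 0.07 and -0.20 ± 0.38 at 6, 24 and 72 h. Both probes were well above background on every array of every group, KO arrays included. The labels do not give the deleted part of Sirt1, and a probe outside it checks nothing. On the tested probe no comparison of restricted with complete medium passed for Sirt1, with values from -0.02 to 0.88. On the further probe Sirt1 rose in restricted medium at 72 h in WT cells (0.56, adjusted p = 0.00108 over all probes) and in KO cells (0.93, adjusted p = 2.64e-06), and did not pass at 6 or 24 h (lowest adjusted p = 0.108).

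**Figure D1:**
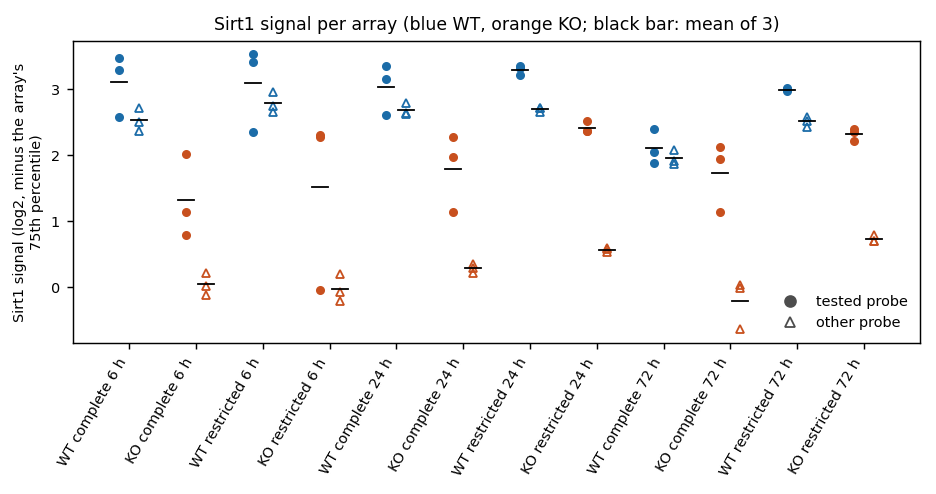
Sirt1 signal on each array by probe, as log2 signal relative to the array's 75th percentile (vertical axis), for the 12 groups (horizontal axis); points are arrays and lines are group means. On the probe outside the gene-level fit, KO means in complete medium lay between -0.20 and 0.29 and WT means between 1.95 and 2.69.

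KO and WT cells were then compared in complete medium, which asks how the lines differed without restriction. Of the 5 lowest genes under the naming rule, 4 were imprinted transcripts, expressed from a single parental copy. Meg3 (-9.07 ± 0.23) and Rian (at least 26.3-fold), maternally expressed noncoding RNAs of the Dlk1-Dio3 region, were lower in KO cells. So were Snrpn (-6.48 ± 0.08) and Snurf (-6.07 ± 0.14), paternally expressed transcripts of the Prader-Willi region. Mbl2, a mannose-binding lectin, was at least 55.9-fold lower at 6 h and at least 47.8-fold lower at 72 h. Higher in KO cells were Abca1 (3.59 ± 0.11), a cholesterol efflux pump, Tenm4 (3.28 ± 0.12), a teneurin, and Cdkn1c (3.11 ± 0.12), an imprinted inhibitor of cyclin-dependent kinases. Cpe (3.11 ± 0.06), a carboxypeptidase encoded on the chromosome of Hmox1, and Lrfn2 (at least 4.22-fold), a synaptic adhesion protein, were higher as well. Of 21 imprinted genes, 6 rose and 13 fell (6 and 13 over the list alone). The imprinted list as a set did not pass (adjusted p = 0.061, 0.129 with estimated correlation), and passed without the genes of 2 chromosomes described with the chromosome medians (adjusted p = 0.00693).

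Germline genes, normally silent outside germ cells, were lower in KO cells as a set. Of 19 germline genes, 1 rose and 12 fell (1 and 12 over the list alone). The set shifted downward (adjusted p = 2.7e-05, 0.0408 with estimated correlation), led by Hormad1 (-2.62 ± 0.12), a meiotic chromosome axis protein, Dazl (-2.29 ± 0.09), a germ-cell RNA-binding protein, Mael (-2.05 ± 0.07), a piRNA pathway protein, and Tex19.1 (-2.45 ± 0.09), a germ-cell gene on the chromosome of Top2a. Similarly, 1 of 9 markers of the 2-cell-like state rose and 5 fell (1 and 5 over the list alone), with adjusted p = 0.0132, 0.152 with estimated correlation. Zscan4c (-3.20 ± 0.16), Tcstv1 (-2.42 ± 0.15), Usp17la (-2.13 ± 0.16) and Tcstv3 (at least 2.81-fold) were lower, the group of transcripts that marks rare ES cells resembling the early embryo. Of 15 interferon genes, 0 rose and 8 fell (0 and 8 over the list alone). This set was lower as a whole (adjusted p = 0.0109, 0.361 with estimated correlation), with Ifi27 (-3.40 ± 0.11), Oas1a (-1.22 ± 0.07) and Ifitm1 (-1.13 ± 0.09) among its members. Of 20 p53 targets, 3 rose and 11 fell (3 and 11 over the list alone). They shifted downward (adjusted p = 0.0203, 0.433 with estimated correlation), through Cdkn1a (-1.39 ± 0.08), a cell cycle inhibitor, and Ccng1 (-0.96 ± 0.06), cyclin G1, on the chromosome of Top2a, while Pmaip1 (1.65 ± 0.12), which encodes the pro-apoptotic protein NOXA, rose.

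Amino acid response genes and cholesterol synthesis genes were higher in KO cells. Of 35 amino acid response genes, 17 rose and 8 fell (18 and 8 over the list alone). The set shifted upward (adjusted p = 0.0237, 0.568 with estimated correlation), and adjusted p = 0.0501 with slide as a fixed block. Atf4 (1.28 ± 0.06), the transcription factor of the response, Atf5 (1.31 ± 0.07), Chac1 (1.28 ± 0.08), a glutathione-degrading enzyme, and Vldlr (1.34 ± 0.11), a lipoprotein receptor, rose, while Asns (-0.50 ± 0.11), asparagine synthetase, and Ddit3 (-0.39 ± 0.08), which encodes CHOP, fell. Of 21 cholesterol synthesis genes, 11 rose and 2 fell (11 and 3 over the list alone). That set shifted upward (adjusted p = 0.0194, 0.237 with estimated correlation), with Cyp51 (0.77 ± 0.08), Sc5d (0.59 ± 0.08) and, on the chromosome of Hmox1, Msmo1 (0.82 ± 0.09) and Mvd (0.54 ± 0.08). Without the genes of that chromosome and of the chromosome of Top2a its adjusted p was 0.0738. Of the preset pluripotency genes, Myc rose (0.80, adjusted p = 1.4e-08) and Sox2 fell (-0.27, adjusted p = 0.00974), while Nanog (-0.09, adjusted p = 0.344) and Pou5f1 (0.06, adjusted p = 0.484) did not pass.

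Over the mean of the 3 times, 9945 of 22446 genes changed, 4984 higher and 4961 lower in KO cells. At 6 h 6269 genes changed (2971 higher, 3298 lower), at 24 h 5808 (2991 and 2817) and at 72 h 7297 (3695 and 3602). Across the times, 1567 genes were higher at all 3, 1740 were lower at all 3, and 252 were called in opposite directions. With slide as a fixed block the counts were 9945 for the mean and 7117, 6240 and 6504 at 6, 24 and 72 h. Normexp gave 3918 (mean), 1160, 1351 and 1896. Within slides 1 to 3, 4 to 6, and 8 and 9, at least 98.9% of genes called at 6, 24 and 72 h kept their sign. Calls came from these same arrays, so selection largely fixes this share. Of the called genes, 50.1% were higher over the mean of times with the 75th percentile as the reference and 66.9% with the median, against 47.4% and 75.3% at 6 h (58.2% with normexp) and 50.6% and 64% at 72 h.

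The same imprinted genes led each time point. Meg3 was -9.09, -9.10 and -9.03 at 6, 24 and 72 h, Snrpn -6.77, -6.38 and -6.28, and Slc38a4, an imprinted amino acid transporter, -6.05 and -6.26 at 24 and 72 h. As a set at 24 h, 5 of 21 imprinted genes rose and 11 fell (6 and 12 over the list alone), with adjusted p = 0.0374, 0.0872 with estimated correlation. That call ended without WT complete-medium 24 h replicate 1 (adjusted p = 0.0956), and the set did not pass at 6 h (adjusted p = 0.0939) or 72 h (adjusted p = 0.0551). At 6 h Ifi202b (at least 17.4-fold), an interferon-induced gene, was lower and Sgce (3.31 ± 0.13), an imprinted sarcoglycan, was higher. At 24 h Cemip (at least 4.37-fold), a hyaluronan-degrading protein, was higher, and at 72 h Igfbp7 (3.78 ± 0.13), an insulin-like growth factor binding protein. At 6 h, 1 of 19 germline genes rose and 9 fell (1 and 11 over the list alone), with adjusted p = 0.000165, 0.0671 with estimated correlation. At 24 h, 2 of 19 germline genes rose and 7 fell (2 and 7 over the list alone), with adjusted p = 0.00519, 0.186 with estimated correlation. At 72 h, 0 of 19 germline genes rose and 13 fell (0 and 13 over the list alone), with adjusted p = 1e-07, 0.0112 with estimated correlation. Likewise at 6 h, 0 of 9 markers of the 2-cell-like state rose and 4 fell (0 and 4 over the list alone), with adjusted p = 0.00199, 0.0671 with estimated correlation. Likewise at 24 h, 0 of 9 such markers rose and 4 fell (1 and 4 over the list alone), with adjusted p = 0.00747, 0.121 with estimated correlation. At 72 h, 0 of 9 such markers rose and 4 fell (0 and 4 over the list alone), with adjusted p = 0.043, 0.274 with estimated correlation. The 72 h call ended with slide as a fixed block (adjusted p = 0.0619) and without KO complete-medium 72 h replicate 3 (0.0738), and the list median on slide 9 was 0.01, against the call. In KO cells at 6 h, 19 of 35 amino acid response genes rose and 6 fell (19 and 7 over the list alone), with adjusted p = 0.000114, 0.277 with estimated correlation. By 24 h, 12 of 35 such genes rose and 4 fell (13 and 6 over the list alone), with adjusted p = 0.0161, 0.526 with estimated correlation. At 72 h the set did not pass, as 8 members rose and 7 fell (8 and 7 over the list alone), with adjusted p = 0.764, 0.907 with estimated correlation. Chac1 (1.07, 1.5, 1.28) and Atf4 (1.46, 1.41, 0.96) rose at all 3 times, and Ddit3 fell at 72 h alone (-1.63, adjusted p = 7.38e-10).

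Cholesterol synthesis, p53 and interferon lists were called at some times. In KO cells at 24 h, 10 of 21 cholesterol synthesis genes rose and 0 fell (10 and 0 over the list alone), with adjusted p = 0.00113, 0.0768 with estimated correlation. At 6 h 7 of 21 cholesterol synthesis genes rose and 1 fell (7 and 1 over the list alone), with adjusted p = 0.0144, 0.204 with estimated correlation. On slide 1 the list median was 0 at 6 h. That 6 h call ended without the genes of the 2 shifted chromosomes (adjusted p = 0.0528), and so did that of glycolysis and hypoxia genes (adjusted p = 0.0685). With those genes, 10 of 22 glycolysis and hypoxia genes rose and 2 fell (11 and 3 over the list alone), with adjusted p = 0.0146, 0.384 with estimated correlation. Ankrd37 (2.58 ± 0.17), a hypoxia-induced gene on the chromosome of Hmox1, Tpi1 (0.95 ± 0.12), a glycolytic enzyme, and Vegfa (0.66 ± 0.10), the vascular growth factor, rose. At 24 h 3 of 20 p53 targets rose and 10 fell (4 and 11 over the list alone), with adjusted p = 0.0322, 0.449 with estimated correlation. At 72 h 2 of 20 p53 targets rose and 11 fell (2 and 12 over the list alone), with adjusted p = 0.00542, 0.317 with estimated correlation. At 24 h 0 of 15 interferon genes rose and 6 fell (0 and 6 over the list alone), with adjusted p = 0.00804, 0.333 with estimated correlation. At 72 h 0 of 15 interferon genes rose and 7 fell (0 and 8 over the list alone), with adjusted p = 0.00677, 0.317 with estimated correlation. Among presets, Mat2a, which makes S-adenosylmethionine, was -0.57 at 6 h (adjusted p = 0.00406), -0.47 at 24 h (adjusted p = 0.0165) and 0.55 at 72 h (adjusted p = 0.00407). The 24 h call ended without KO complete-medium 24 h replicate 2 (-0.44, adjusted p = 0.0609) and the 72 h call without KO complete-medium 72 h replicate 1 (0.37, adjusted p = 0.0557).

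Genes of 2 chromosomes shifted together between the lines. The 821 measured genes on the chromosome of Hmox1, which encodes heme oxygenase, had a median of 0.41 log2 units in KO against WT, relative to all 16162 genes with a position, and 449 of them rose while 84 fell. The 1355 genes on the chromosome of Top2a, a topoisomerase of dividing cells, had a median of -0.30, and 83 rose while 722 fell. The medians at 6, 24 and 72 h were 0.41, 0.35 and 0.41 for the first and -0.33, -0.34 and -0.31 for the second. Across arrays, the median on the chromosome of Hmox1 lay between 0.13 and 0.24 in KO and between -0.21 and -0.13 in WT arrays, and that on the chromosome of Top2a between -0.26 and -0.12 in KO and between 0.11 and 0.26 in WT arrays. Medians of the other 18 chromosomes lay between -0.05 and 0.09. A 2-sided permutation test of KO and WT labels of arrays gave p = 1e-05 for each, the smallest 100000 permutations can give. It did not test gene position. Both chromosomes were picked after their medians had been seen. Without their genes, 8551 genes changed over the mean of times, 5172 at 6 h, 4795 at 24 h and 6216 at 72 h.

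**Figure D2:**
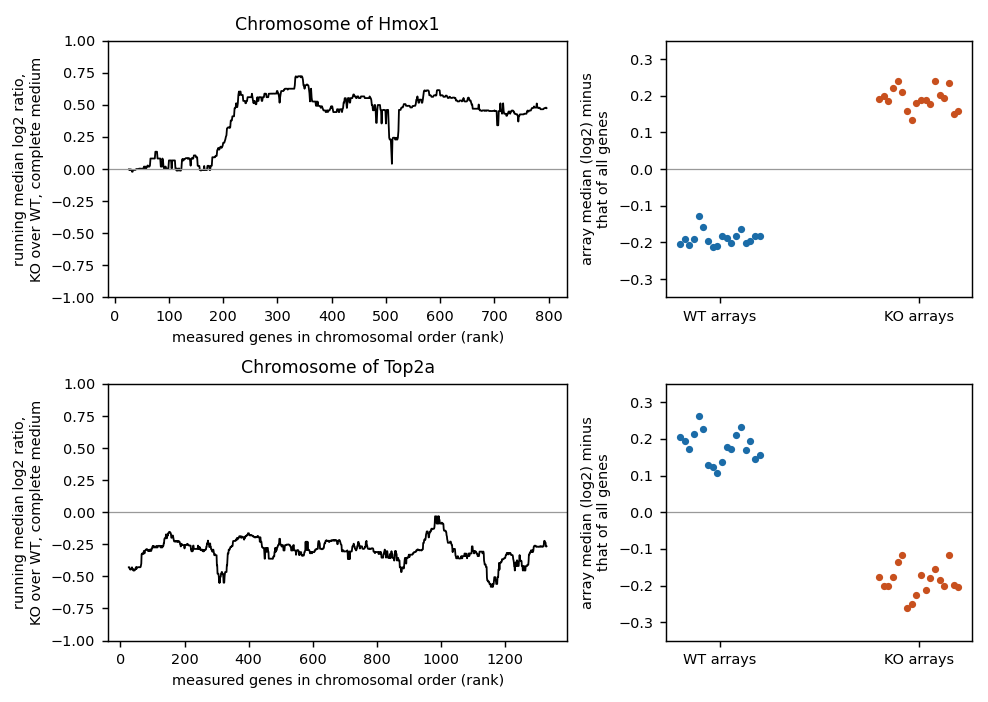
Difference between KO and WT in complete medium along the chromosomes of Hmox1 and Top2a (running median over 51 genes in chromosomal order, log2, relative to all genes) and the median of each array on both. KO arrays lay between 0.13 and 0.24 on the chromosome of Hmox1 and between -0.26 and -0.12 on that of Top2a, apart from all WT arrays.

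Restricted and complete medium were compared in WT cells at each time, which asks how ES cells respond to low methionine. After 6 h, p53 targets rose and markers of the primed epiblast, the pluripotent tissue just before gastrulation, fell. Of 20 p53 targets, 12 rose and 0 fell (13 and 0 over the list alone). The set shifted upward (adjusted p = 3.59e-17, 0.00177 with estimated correlation), with Btg2 (1.95 ± 0.10), an antiproliferative gene, Plk2 (1.63 ± 0.17), a stress-induced kinase, Cdkn1a (1.40 ± 0.13) and Trp53inp1 (1.28 ± 0.15), a p53-induced nuclear protein. Of 15 primed epiblast markers, 0 rose and 7 fell (0 and 7 over the list alone). This set shifted downward (adjusted p = 8.16e-05, 0.00955 with estimated correlation), and Lef1 (-1.08 ± 0.17), a Wnt pathway transcription factor, Fgf15 (-0.90 ± 0.14), a fibroblast growth factor, and Sall2 (-0.59 ± 0.09) were among the members that fell. At the same time 8 of 35 amino acid response genes rose and 2 fell (11 and 3 over the list alone), with adjusted p = 0.00767, 0.454 with estimated correlation. Ddit4 (1.38 ± 0.15), an inhibitor of mTORC1, Atf4 (0.90 ± 0.11), Stc2 (0.85 ± 0.11) and Slc1a4 (0.58 ± 0.09), a neutral amino acid transporter, rose. Mat2a (0.83 ± 0.15) rose at this first time point (adjusted p = 0.000236), and Neurod1 (2.31 ± 0.34), a neuronal transcription factor, was among the highest named genes.

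In all, 2694 genes changed in WT cells at 6 h, 1325 higher and 1369 lower. With slide as a fixed block 3403 genes were called. At least 99.8% of calls kept their sign on slides 1, 2 and 3, which selection largely fixes too. Normexp background correction gave 51 genes and the fit of only the groups of the contrast 1174. The median of the amino acid response list was -0.02 on slide 1 and -0.04 on slide 3, against the direction of its call. Higher genes made up 49.2% of the calls, or 75.8% with the median as the reference.

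After 24 h in restricted medium, p53 targets and amino acid response genes rose and cell cycle, hypoxia and sterol genes fell in WT cells. Of 20 p53 targets, 17 rose and 1 fell (17 and 1 over the list alone). The set shifted upward (adjusted p = 1.71e-13, 0.00434 with estimated correlation), led by Btg2 (3.86 ± 0.10), Perp (3.68 ± 0.09), a p53-induced membrane protein, Gdf15 (3.28 ± 0.13), a stress-induced cytokine, and Cdkn1a (2.94 ± 0.13). Of 35 amino acid response genes, 24 rose and 4 fell (24 and 4 over the list alone). They shifted upward (adjusted p = 1.05e-06, 0.148 with estimated correlation), with Atf3 (4.23 ± 0.14), Ddit3 (3.09 ± 0.14), Ddit4 (2.73 ± 0.15) and Atf4 (2.08 ± 0.11). By 24 h 7 of 9 markers of the 2-cell-like state rose and 0 fell (7 and 0 over the list alone), with adjusted p = 0.000569, 0.0413 with estimated correlation. Similarly, 15 of 19 germline genes rose and 1 fell (15 and 1 over the list alone), with adjusted p = 1.72e-05, 0.0367 with estimated correlation. Usp17la (3.64 ± 0.28), a deubiquitinase of the 2-cell-like state, Zscan4c (3.47 ± 0.28), a telomere regulator, Tex101 (3.47 ± 0.35), a sperm surface protein, and Asz1 (at least 7.18-fold), a piRNA pathway protein, were among them. Of 18 endoderm markers, 10 rose and 1 fell (11 and 1 over the list alone). This marker set of another cell type rose too (adjusted p = 0.00244, 0.0459 with estimated correlation), through Afp (at least 9.03-fold), alpha-fetoprotein, Cubn (3.02 ± 0.37), a receptor, and Gata6 (2.73 ± 0.15), a transcription factor of primitive endoderm, while Sox7 (-1.59 ± 0.18) fell.

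Among lower sets at 24 h in WT cells, 17 of 22 measured cell cycle genes fell and 1 rose (1 and 17 over the list alone), with adjusted p = 0.000135, 0.0812 with estimated correlation. Ccnd2 (-2.53 ± 0.12), cyclin D2, and Ccne1 (-1.96 ± 0.13), cyclin E1, fell, and Cdkn2b (2.61 ± 0.12), a cyclin-dependent kinase inhibitor, rose. Of 22 glycolysis and hypoxia genes, 2 rose and 15 fell (2 and 16 over the list alone). They shifted downward (adjusted p = 5.49e-06, 0.0671 with estimated correlation), with Egln3 (-3.06 ± 0.11), an oxygen-sensing prolyl hydroxylase, Bnip3 (-2.98 ± 0.10), a hypoxia-induced mitophagy receptor, Pdk1 (-2.53 ± 0.09), pyruvate dehydrogenase kinase, and Tpi1 (-2.25 ± 0.12). For sterols, 1 of 21 cholesterol synthesis genes rose and 13 fell (1 and 14 over the list alone), with adjusted p = 0.000502, 0.0599 with estimated correlation. Dhcr7 (-1.41 ± 0.14), Fdps (-1.08 ± 0.10) and Sqle (-0.86 ± 0.10), enzymes of the pathway, fell. At 24 h 1 of 17 Nrf2 and glutathione genes rose and 10 fell (1 and 10 over the list alone), with adjusted p = 0.0114, 0.368 with estimated correlation. Of pluripotency lists, 1 of 28 naive pluripotency genes rose and 14 fell (2 and 16 over the list alone), with adjusted p = 0.0188, 0.384 with estimated correlation. That call ended without WT complete-medium 24 h replicate 1 (adjusted p = 0.0506). By then 5 of 15 primed epiblast markers rose and 9 fell (5 and 9 over the list alone), with adjusted p = 0.00982, 0.0723 with estimated correlation. Lef1 (-2.88 ± 0.17), Fgf15 (-2.56 ± 0.14), Dnmt3b (-1.47 ± 0.10) and Dnmt3a (-1.34 ± 0.10), the latter pair de novo DNA methyltransferases, fell. Pou5f1 (-0.65 ± 0.11) fell (adjusted p = 1.11e-05) and Mat2a (0.87 ± 0.15) rose (adjusted p = 1.86e-05). Ces2e (at least 33.1-fold), a carboxylesterase, Gpx6 (6.12 ± 0.35), a glutathione peroxidase, Mgst2 (at least 27.7-fold), a glutathione transferase, and the keratins Krt33a (at least 17.8-fold) and Krt15 (5.61 ± 0.55) were the highest named genes, and Aire (-4.75 ± 0.16), a transcriptional regulator of the thymus, and Aoc3 (at least 12-fold), an amine oxidase, were among the lowest.

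By 72 h the hypoxia and sterol sets of WT cells had fallen and germline and early-embryo transcripts had risen. Of 22 glycolysis and hypoxia genes, 1 rose and 20 fell (1 and 20 over the list alone). The set shifted downward (adjusted p = 2.13e-13, 0.00391 with estimated correlation), with Egln3 (-5.76 ± 0.11), Bnip3 (-5.44 ± 0.10), Pdk1 (-2.84 ± 0.09) and Pgk1 (-2.79 ± 0.08), a glycolytic kinase. Of 21 cholesterol synthesis genes, 0 rose and 19 fell (0 and 19 over the list alone). They shifted downward (adjusted p = 7.81e-11, 0.00151 with estimated correlation), with Dhcr7 (-2.90 ± 0.14), Fdps (-1.93 ± 0.10) and Sqle (-1.65 ± 0.10). Conversely, 8 of 9 markers of the 2-cell-like state rose and 1 fell (8 and 1 over the list alone), with adjusted p = 1.45e-05, 0.0121 with estimated correlation. Usp17la (6.05 ± 0.28), Zscan4c (5.92 ± 0.28), Tcstv1 (5.87 ± 0.25) and Tcstv3 (5.79 ± 0.25) rose. Among the highest named genes were Pramel7 (at least 62.4-fold) and Pramel39 (at least 85.9-fold), members of a gene family expressed in germ cells and early embryos, H2bfm (at least 54.3-fold), a histone variant, and Clec10a (at least 41.2-fold), a lectin. At 72 h, too, 16 of 19 germline genes rose and 1 fell (16 and 1 over the list alone), with adjusted p = 6.94e-06, 0.0282 with estimated correlation. Dazl (2.02 ± 0.15), Tdrd1 (2.09 ± 0.15), a piRNA pathway protein, and Syce1 (1.59 ± 0.12), a synaptonemal complex protein, rose.

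Of 20 p53 targets, 16 rose and 0 fell (16 and 0 over the list alone). They remained higher in restricted medium at 72 h (adjusted p = 9.13e-09, 0.025 with estimated correlation), with Perp (3.95 ± 0.09), Plk2 (3.72 ± 0.17) and Ccng1 (2.05 ± 0.11). Of 18 endoderm markers, 11 rose and 2 fell (11 and 2 over the list alone). That set stood higher (adjusted p = 0.00126, 0.0367 with estimated correlation), with Afp (at least 16.3-fold), Dab2 (2.97 ± 0.20), an endocytic adaptor, Gata6 (2.52 ± 0.15) and Foxa2 (2.45 ± 0.19). By 72 h 3 of 15 primed epiblast markers rose and 9 fell (3 and 9 over the list alone), with adjusted p = 0.0307, 0.152 with estimated correlation. In folate metabolism, 1 of 18 serine and one-carbon genes rose and 10 fell (1 and 11 over the list alone), with adjusted p = 0.0132, 0.241 with estimated correlation. Mthfd1l (-1.37 ± 0.13) and Gldc (-1.31 ± 0.10), mitochondrial folate and glycine enzymes, fell. Again 3 of 17 Nrf2 and glutathione genes rose and 10 fell (3 and 10 over the list alone), with adjusted p = 0.0194, 0.418 with estimated correlation. The amino acid response list did not pass at 72 h, as 11 of 35 measured members rose and 15 fell (11 and 15 over the list alone), with adjusted p = 0.787, 0.915 with estimated correlation. For another cell type, 7 of 12 trophoblast markers rose and 2 fell (8 and 2 over the list alone), with adjusted p = 0.043, 0.394 with estimated correlation. Gata3 (at least 23.4-fold) and Plac1 (at least 8.28-fold) rose, and the call ended without WT complete-medium 72 h replicate 1 (adjusted p = 0.0662). Among preset genes Mat2a (2.55 ± 0.15), Myc (1.84 ± 0.15) and Nanog (1.09 ± 0.12) rose, Ddit3 (0.66 ± 0.14) and Trib3 (0.86 ± 0.14), a pseudokinase of the stress response, rose, and Pou5f1 (-0.59 ± 0.11) and Chac1 (-0.52 ± 0.14) fell.

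The counts in WT cells were 9766 genes at 24 h (4654 higher, 5112 lower) and 12357 at 72 h (6368 and 5989). Across the 3 times, 869 genes were higher at every one, 659 were lower at every one, and 1051 were called in opposite directions. At 24 and 72 h the media lay on different slides, and slide as a random block gave 9712 and 12086 genes. Normexp gave 3854 and 4587. Higher genes made up 47.7% of the calls at 24 h and 51.5% at 72 h, or 33% and 35.1% with the median as the reference.

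**Figure D3:**
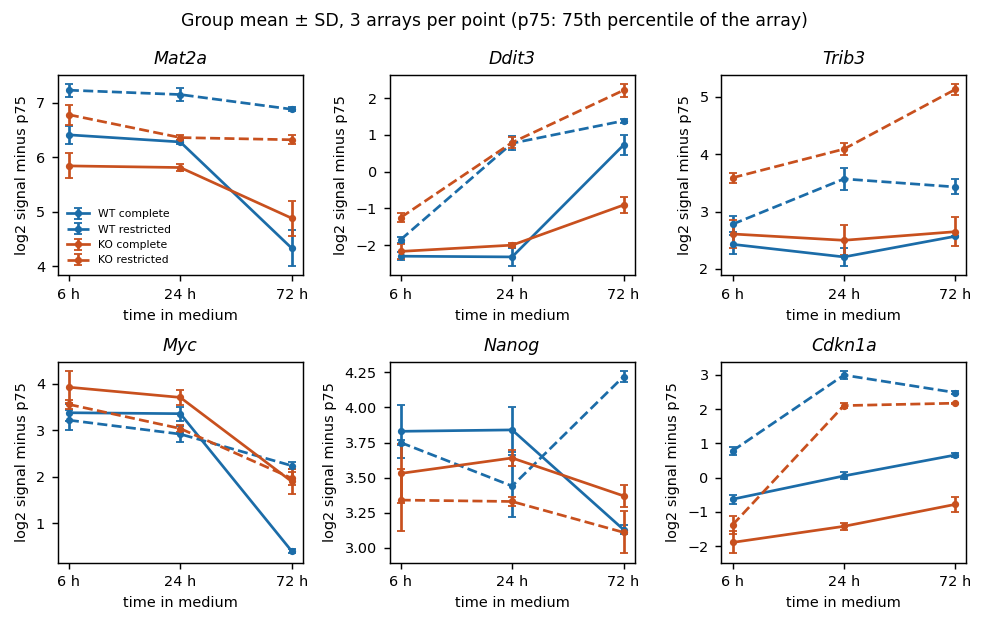
Mean log2 signal relative to the array's 75th percentile (vertical axis) ± SD of 3 arrays for Mat2a, Ddit3, Trib3, Myc, Nanog and Cdkn1a at 6, 24 and 72 h (horizontal axis), by genotype and medium. In WT cells Mat2a was higher by 2.55 in restricted than in complete medium at 72 h, and in KO cells by 1.43.

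The same media were compared in KO cells. After 6 h, markers of the primed epiblast fell and amino acid response genes rose. Of 15 primed epiblast markers, 0 rose and 9 fell (1 and 10 over the list alone). The set shifted downward (adjusted p = 3.33e-06, 0.00274 with estimated correlation), with Lef1 (-1.42 ± 0.17), Zic2 (-1.22 ± 0.20), Foxd3 (-0.72 ± 0.14) and Fgf15 (-0.71 ± 0.14). Of 35 amino acid response genes, 12 rose and 1 fell (13 and 3 over the list alone). They shifted upward (adjusted p = 0.000106, 0.274 with estimated correlation), with Trib3 (0.98 ± 0.14), Slc1a4 (0.86 ± 0.09), Atf4 (0.78 ± 0.11) and Stc2 (0.72 ± 0.11). In KO cells at 6 h 8 of 20 p53 targets rose and 1 fell (10 and 1 over the list alone), with adjusted p = 0.000115, 0.148 with estimated correlation. Trp53inp1 (0.74 ± 0.15) and Bbc3 (0.67 ± 0.13), which encodes the pro-apoptotic protein PUMA, rose. Of the presets Mat2a (0.94 ± 0.15), Ddit3 (0.92 ± 0.14) and Chac1 (0.75 ± 0.14) rose as well.

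In KO cells at 6 h the test gave 2614 genes, 1239 higher and 1375 lower. The count was 1398 without KO complete-medium 6 h replicate 3 and 4083 without replicate 1 of that group. Normexp gave 32 genes and the fit of only the groups of the contrast 1. With slide as a fixed block it was 3179. At least 96.8% of calls kept their sign on slides 1, 2 and 3, again largely fixed by selection. Higher genes made up 47.4% of the calls, or 35.2% with the median as the reference.

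At 24 h in KO cells p53 targets and amino acid response genes rose and sterol and hypoxia genes fell. Of 20 p53 targets, 17 rose and 1 fell (17 and 2 over the list alone). They shifted upward (adjusted p = 8.52e-18, 0.00151 with estimated correlation), with Cdkn1a (3.53 ± 0.13), Gdf15 (2.93 ± 0.13), Btg2 (2.55 ± 0.10) and Perp (2.29 ± 0.09). Of 35 amino acid response genes, 24 rose and 2 fell (25 and 3 over the list alone). This set shifted upward (adjusted p = 1.96e-12, 0.0282 with estimated correlation), with Ddit3 (2.79 ± 0.14), Ddit4 (2.42 ± 0.15), Atf3 (2.07 ± 0.14) and Slc1a4 (1.46 ± 0.09). Of 21 cholesterol synthesis genes, 1 rose and 19 fell (1 and 19 over the list alone). They shifted downward (adjusted p = 1.65e-08, 0.00361 with estimated correlation), with Nsdhl (-2.19 ± 0.17), a sterol dehydrogenase, Dhcr7 (-1.58 ± 0.14) and Fdps (-1.45 ± 0.10). Of 22 glycolysis and hypoxia genes, 2 rose and 16 fell (2 and 16 over the list alone). They were lower as a set (adjusted p = 1.09e-08, 0.0223 with estimated correlation), with Bnip3 (-2.49 ± 0.10), Egln3 (-1.96 ± 0.11) and Pdk1 (-1.86 ± 0.09). Also, 12 of 19 germline genes rose and 2 fell (12 and 2 over the list alone), with adjusted p = 0.00143, 0.129 with estimated correlation. Further, 1 of 22 cell cycle genes rose and 11 fell (1 and 11 over the list alone), with adjusted p = 0.0028, 0.186 with estimated correlation. Also at 24 h 2 of 17 Nrf2 and glutathione genes rose and 8 fell (3 and 9 over the list alone), with adjusted p = 0.0129, 0.376 with estimated correlation. Also, 1 of 10 polyamine genes rose and 7 fell (1 and 7 over the list alone), with adjusted p = 0.0365, 0.296 with estimated correlation. Of the 2-cell-like markers 2 of 9 rose and 0 fell (2 and 0 over the list alone), and the set did not pass (adjusted p = 0.142, 0.438 with estimated correlation). Of endoderm markers 4 of 18 rose and 1 fell (4 and 1 over the list alone), and that set did not pass either (adjusted p = 0.256, 0.487 with estimated correlation). Gpx6 (at least 11.2-fold), Anxa8 (5.21 ± 0.13), an annexin, and Tap1 (at least 18.9-fold), a peptide transporter of antigen presentation, were among the highest named genes, and Fgf5 (at least 4.67-fold), a primed epiblast growth factor, Ppp1r3g (at least 6.51-fold), a glycogen-targeting phosphatase subunit, and Lrfn2 (at least 4.82-fold) among the lowest.

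At 72 h in KO cells sterol and hypoxia genes fell and germline genes rose. Of 21 cholesterol synthesis genes, 0 rose and 19 fell (0 and 19 over the list alone). They shifted downward (adjusted p = 2.52e-15, 0.000362 with estimated correlation), with Dhcr7 (-2.72 ± 0.14), Nsdhl (-2.47 ± 0.17) and Fdps (-1.53 ± 0.10). Of 22 glycolysis and hypoxia genes, 1 rose and 19 fell (1 and 19 over the list alone). That set shifted downward (adjusted p = 8.01e-15, 0.00272 with estimated correlation), with Egln3 (-4.84 ± 0.11), Bnip3 (-4.46 ± 0.10), Pdk1 (-2.49 ± 0.09) and Pgk1 (-2.27 ± 0.08). Of 19 germline genes, 17 rose and 1 fell (17 and 1 over the list alone). The germline set shifted upward (adjusted p = 3.38e-11, 0.00254 with estimated correlation), with Taf7l (4.05 ± 0.21), a germ-cell transcription factor, Mael (3.04 ± 0.12), Dazl (2.81 ± 0.15) and Tdrd1 (2.65 ± 0.15). With these, 7 of 9 markers of the 2-cell-like state rose and 0 fell (7 and 0 over the list alone), with adjusted p = 1.8e-05, 0.013 with estimated correlation. Zscan4c (6.49 ± 0.28), Usp17la (5.82 ± 0.28) and Tcstv1 (4.38 ± 0.25) rose. Of 20 p53 targets, 16 rose and 0 fell (16 and 0 over the list alone). They shifted upward (adjusted p = 2.01e-13, 0.00434 with estimated correlation), with Plk2 (4.01 ± 0.17) and Cdkn1a (2.95 ± 0.13). Of 35 amino acid response genes, 21 rose and 2 fell (22 and 2 over the list alone). The set stayed higher (adjusted p = 4.3e-07, 0.129 with estimated correlation), with Atf5 (3.14 ± 0.13), Ddit3 (3.12 ± 0.14), Cebpb (2.61 ± 0.15) and Trib3 (2.49 ± 0.14). Rhox2a (5.84 ± 0.47), a reproductive homeobox gene, Pdha2 (5.71 ± 0.47), a testis form of pyruvate dehydrogenase, and Neurod1 (at least 10.5-fold) were among the highest named genes, and Aoc3 (at least 15.1-fold) and Col8a2 (at least 11.6-fold), a collagen, among the lowest.

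In KO cells 8466 genes changed at 24 h (3659 higher, 4807 lower) and 9642 at 72 h (5273 and 4369). Across the 3 times 655 genes were higher at every one, 606 were lower at every one, and 622 were called in opposite directions. Normexp gave 2935 and 2918. Slide as a random block gave 8394 genes at 24 h and 9466 at 72 h. Higher genes made up 54.7% of the calls at 72 h, or 35.1% with the median as the reference.

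**Figure D4:**
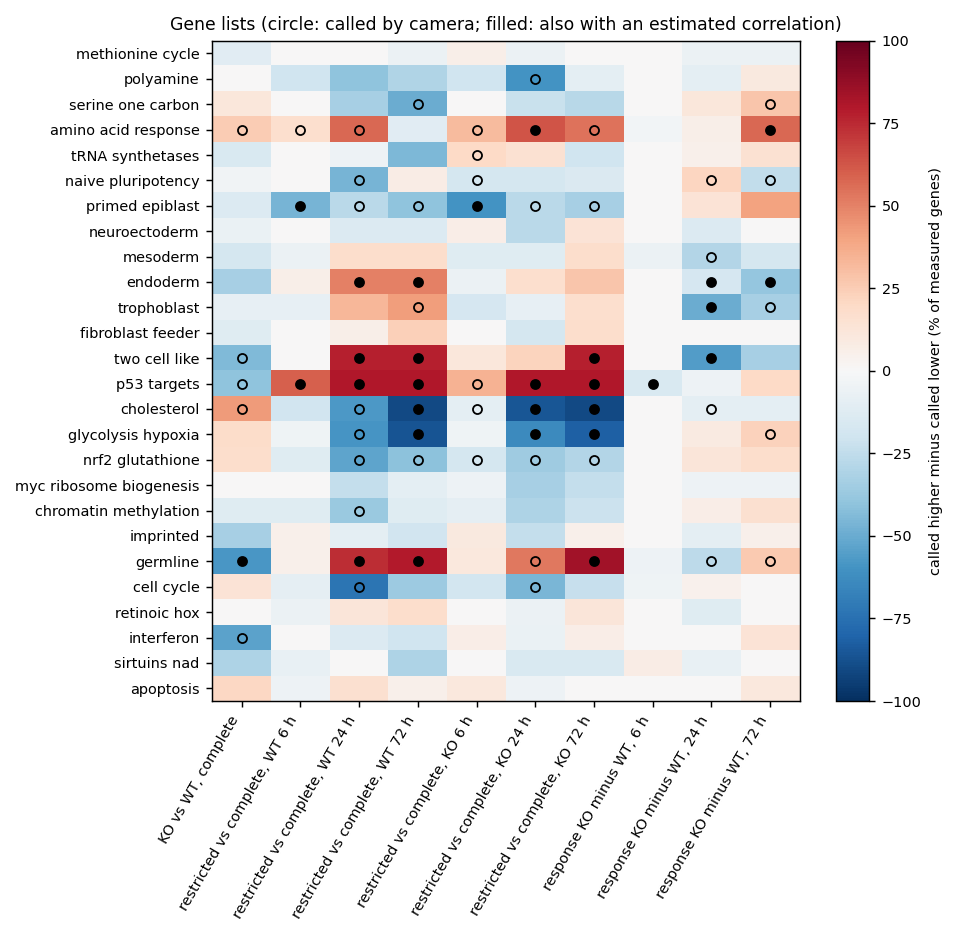
Percent of each list's measured members called higher minus percent lower (colour) by comparison (horizontal axis). These are KO against WT in complete medium, restricted against complete medium at each time and its difference, KO minus WT. Open circles mark camera calls and filled those also made with estimated correlation. At 72 h 19 of 21 cholesterol synthesis genes fell in each genotype.

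The responses of both genotypes were set against each other by testing the difference of the medium effect, KO minus WT. Across genes, which are not independent replicates, the responses correlated at 0.3138, 0.7078 and 0.7628 (Pearson) and 0.3322, 0.6996 and 0.7532 (Spearman) at 6, 24 and 72 h. Genes higher in both genotypes numbered 557, 2752 and 3836, where independent lists would share 73.1, 758.7 and 1496. Genes lower in both numbered 535, 3571 and 3377, where independent lists would share 83.9, 1094.8 and 1165.7, and 13, 184 and 349 were called in opposite directions. No array entered both responses, but WT and KO arrays shared slides and their replicate deviations correlated in restricted medium, which the expected overlaps leave out.

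At 72 h the amino acid response differed between the genotypes. The change was more positive in KO than in WT cells for 20 of 35 measured genes and more negative for 0 (22 and 1 over the list alone), with adjusted p = 1.56e-12, 0.0282 with estimated correlation. The difference was 2.46 for Ddit3 (0.66 in WT, 3.12 in KO), 1.63 for Trib3 (0.86 and 2.49) and 1.31 for Chac1 (-0.52 and 0.79). It was -1.12 for Mat2a (2.55 and 1.43), -1.77 for Myc (1.84 and 0.07) and -1.35 for Nanog (1.09 and -0.26). Endoderm markers differed the other way, with a more positive change in KO cells for 1 and a more negative for 8 of 18 (1 and 11 over the list alone) and adjusted p = 0.000127, 0.0144 with estimated correlation. Sox7 (-2.17), Col4a1 (-1.68) and Afp (-4.82) were among them, and Afp was well above background in no array of some groups. In all 4131 genes differed at 72 h (2177 positive, 1954 negative), and 441 with normexp.

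At 24 h, 2586 genes differed (1003 positive, 1583 negative), and 90 with normexp. The difference was negative for trophoblast markers (6 of 12 negative, 0 positive, 0 positive and 6 negative over the list alone), with adjusted p = 2.1e-05, 0.0413 with estimated correlation. Cdx2, a trophoblast transcription factor, was -1.97. Markers of the 2-cell-like state were negative for 5 of 9 and positive for 0 (0 and 5 over the list alone), with adjusted p = 7.86e-05, 0.0222 with estimated correlation. Atf4 rose less in KO (1.47) than in WT cells (2.08), a difference of -0.61 (adjusted p = 0.00838). At 6 h 172 genes differed (75 positive, 97 negative), and the count was 270 with slide as a fixed block, 269 with slide as a random block, 101 without WT restricted-medium 6 h replicate 1 and 332 without KO complete-medium 6 h replicate 1. It was 1 with only the groups of the contrast and 0 with normexp in limma, where 297 genes had an unadjusted p under 0.05. The p53 targets differed at 6 h, with 3 of 20 negative and 0 positive (0 and 9 over the list alone) and adjusted p = 5.34e-10, 0.0151 with estimated correlation. Btg2 was -1.48, from 1.95 in WT and 0.47 in KO cells. Positive differences made up 43.6% of the calls at 6 h and 38.8% at 24 h, or 7.07% and 55.3% with the median as the reference and 31.9% with quantile normalization at 6 h.

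The response at 72 h was set against that at 6 h within each genotype. In WT cells 8909 genes differed (5123 more positive at 72 h, 3786 more negative), and in KO cells 6084 (3345 and 2739). With normexp the counts were 1881 and 1116. Hypoxia genes moved down, with Egln3 at -5.76 in WT and -4.78 in KO cells and Bnip3 at -5.16 and -4.09. Markers of the 2-cell-like state moved up, with Zscan4c at 5.53 and 6.80. The response was more positive at 72 h than at 6 h for Trib3 (1.5) and Ddit3 (2.20) in KO cells and for Mat2a (1.72), Myc (2.00) and Nanog (1.16) in WT cells. Of these, Myc (adjusted p = 0.594) and Nanog (adjusted p = 0.782) had not passed in WT cells at 6 h. Positive differences made up 57.5% of the calls in WT and 55% in KO cells, or 30% and 37.3% with the median as the reference and 43.9% with normexp in WT cells.

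Over all 390 pairs of list and comparison, camera called 104, and 39 of them held with an estimated correlation. No call was made in any comparison for the methionine cycle (lowest adjusted p = 0.31), neuroectoderm (0.406), fibroblast and feeder markers (0.351), ribosome biogenesis (0.138), retinoic acid and Hox genes (0.438), sirtuins and NAD enzymes (0.406) or apoptosis genes (0.212). Chromatin and DNA methylation enzymes were called once, in WT cells at 24 h (2 higher, 14 lower of 32, 2 and 14 over the list alone), with adjusted p = 0.03, 0.152 with estimated correlation. That call ended without WT complete-medium 24 h replicate 1 (adjusted p = 0.0713), and the difference between the genotypes did not pass (adjusted p = 0.22). In all, 19 list calls ended without a single array, some of them not described here.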

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

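Tests chosen only after the result was seen were those of the remaining parts of the chromosome of Hmox1, the correlations of the 24 h and 72 h responses, the choice of the chromosomes of Hmox1 and Top2a, the test of imprinted genes outside the regions of Meg3 and Snrpn, and the splits of the differences of responses made with the shared medium response removed.

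The difference of the medium response between KO and WT cells, tested as an interaction, brought 172 genes at 6 h to attention. Positive differences included Acta1 (2.70), Dmc1 (2.41), Slc16a4 (2.12), Dock10 (2.08) and B3galt1 (1.80), and negative ones Slc3a1 (-3.11), Neurod1 (-2.35), Rprm (-2.06) and Dbx2 (-2.04). The calls of Dock10, Neurod1 and Dbx2 held without any single array, and the others ended, as with Acta1 (adjusted p = 0.127 without WT complete-medium 6 h replicate 2), Dmc1 (adjusted p = 0.108 without WT restricted-medium 6 h replicate 1), Slc16a4 (adjusted p = 0.118 without WT restricted-medium 6 h replicate 3), B3galt1 (adjusted p = 0.151 without WT restricted-medium 6 h replicate 1), Slc3a1 (adjusted p = 0.0621 without WT restricted-medium 6 h replicate 1) and Rprm (adjusted p = 0.0503 without WT restricted-medium 6 h replicate 1). Acta1, Slc16a4, Dock10 and B3galt1 changed sign with normexp, and Slc3a1 and Slc16a4 were well above background in no array of 3 of the 4 groups, Acta1 and Neurod1 in none of 2, and B3galt1, Dbx2 and Dock10 in none of 1. The p53 targets differed as a set (adjusted p = 5.34e-10, 0.0151 with estimated correlation).

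At 24 h the same test gave 2586 genes. Positive differences included Ctxn3 (4.31), Lrrc4c (3.58), Nrg3os (3.39), Cdh4 (3.13) and Sdk1 (3.10). Negative ones included Wdr72 (-5.77), Afp (-5.54), Themis3 (-5.33), Usp18 (-5.27) and Asz1 (-4.95), and Atf4 was -0.61. Of these, Ctxn3, Lrrc4c, Nrg3os, Sdk1, Afp, Themis3, Usp18 and Asz1 were well above background in no array of 3 of the 4 groups and Wdr72 in none of 2, so those sizes are uncertain. Lists with a negative difference were trophoblast (adjusted p = 2.1e-05, 0.0413 with estimated correlation), the 2-cell-like state (adjusted p = 7.86e-05, 0.0222 with estimated correlation), endoderm (adjusted p = 0.00164, 0.0407 with estimated correlation), mesoderm (adjusted p = 0.0126, 0.121 with estimated correlation), cholesterol synthesis (adjusted p = 0.0131, 0.192 with estimated correlation) and germline (adjusted p = 0.0286, 0.333 with estimated correlation), the last ending without WT complete-medium 24 h replicate 3 (adjusted p = 0.0819). Naive pluripotency genes had a positive one (adjusted p = 0.00465, 0.274 with estimated correlation), with 6 of 28 members positive and 0 negative (8 and 0 over the list alone), and list medians were -0.42 in WT and -0.14 in KO cells.

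At 72 h 4131 genes differed. Positive differences included Car6 (5.15), Lrrc4c (4.44), Sdk1 (3.86), Efcab6 (3.71) and Mbp (3.50), and negative ones Glipr1 (-5.26), Themis3 (-4.87), Afp (-4.82), Lypd9 (-4.53) and Clec10a (-4.46). Among presets Ddit3 was 2.46, Trib3 1.63, Chac1 1.31, Mat2a -1.12, Nanog -1.35 and Myc -1.77. Amino acid response genes (adjusted p = 1.56e-12, 0.0282 with estimated correlation) and germline genes (adjusted p = 0.0132, 0.259 with estimated correlation) had a positive difference. Endoderm (adjusted p = 0.000127, 0.0144 with estimated correlation) and naive pluripotency (adjusted p = 0.0139, 0.368 with estimated correlation) had a negative one, the latter led by Myc and Nanog. Glycolysis and hypoxia genes had a positive one (adjusted p = 0.0169, 0.394 with estimated correlation), with 7 of 22 positive and 2 negative (10 and 2 over the list alone), and that call ended without KO complete-medium 72 h replicate 3 (adjusted p = 0.0629). Serine and one-carbon genes had a positive one (adjusted p = 0.0286, 0.317 with estimated correlation), with 5 of 18 positive and 0 negative (5 and 0 over the list alone), and that call ended without WT restricted-medium 72 h replicate 3 (adjusted p = 0.0592). Trophoblast markers had a negative one (adjusted p = 0.0471, 0.407 with estimated correlation), with 1 of 12 positive and 5 negative (1 and 6 over the list alone), and that call ended without KO complete-medium 72 h replicate 1 (adjusted p = 0.111) and with slide as a random (0.0508) or fixed block (0.159). Themis3 and Afp were well above background in no array of 3 of the 4 groups, Glipr1, Lrrc4c and Lypd9 in none of 2, and Clec10a and Efcab6 in none of 1, so those sizes are uncertain.

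Within WT cells the response at 72 h minus that at 6 h differed from 0 for 8909 genes. Positive were Pramel7 (7.26), Pramel39 (7.02), H2bfm (6.43), Clec10a (6.41) and Pramel6 (6.26), and negative Egln3 (-5.76), Aoc3 (-5.74), Zfp174 (-5.17), Bnip3 (-5.16) and Tpsg1 (-4.97). Presets were Mat2a (1.72), Myc (2.00), Nanog (1.16), Pou5f1 (-0.75), Trib3 (0.51) and Chac1 (-0.49). The call of Trib3 ended without WT restricted-medium 6 h replicate 1 (adjusted p = 0.116) and that of Chac1 without WT complete-medium 72 h replicate 1 (adjusted p = 0.122), and each ended without several other arrays. Lists that moved down were glycolysis and hypoxia (adjusted p = 3.47e-17, 0.00151 with estimated correlation), cholesterol synthesis (adjusted p = 4.99e-12, 0.00125 with estimated correlation), serine and one-carbon (adjusted p = 0.0138, 0.246 with estimated correlation), aminoacyl-tRNA synthetases (adjusted p = 0.0134, 0.195 with estimated correlation) and Nrf2 and glutathione genes (adjusted p = 0.0272, 0.438 with estimated correlation), the last ending without WT restricted-medium 6 h replicate 1 (adjusted p = 0.0568). Lists that moved up were the 2-cell-like state (adjusted p = 1.29e-05, 0.012 with estimated correlation), germline (adjusted p = 2.55e-05, 0.0407 with estimated correlation), p53 targets (adjusted p = 0.000341, 0.182 with estimated correlation), endoderm (adjusted p = 0.00298, 0.051 with estimated correlation) and trophoblast (adjusted p = 0.0175, 0.299 with estimated correlation). H2bfm, Clec10a, Aoc3 and Zfp174 were well above background in no array of 2 of the 4 groups, and Pramel7, Pramel39, Pramel6 and Tpsg1 in none of 1, so those sizes are uncertain.

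Within KO cells the corresponding difference was called for 6084 genes. Positive were Zscan4c (6.80), Neurod1 (5.46), Usp17la (5.32), Rhox13 (5.07) and Lrfn5 (4.92), and negative Egln3 (-4.78), Tpsg1 (-4.53), Aoc3 (-4.45), Ppp1r3g (-4.39) and Col8a2 (-4.27). Presets were Ddit3 (2.20), Trib3 (1.5) and Pou5f1 (-0.92). Lists that moved up were amino acid response (adjusted p = 0.00131, 0.384 with estimated correlation), the 2-cell-like state (adjusted p = 7.83e-06, 0.0107 with estimated correlation), p53 targets (adjusted p = 3.01e-14, 0.00361 with estimated correlation) and germline (adjusted p = 4.99e-12, 0.00177 with estimated correlation). Cholesterol synthesis (adjusted p = 3.23e-15, 0.000362 with estimated correlation) and glycolysis and hypoxia (adjusted p = 8.99e-19, 0.00125 with estimated correlation) moved down. So did aminoacyl-tRNA synthetases (adjusted p = 0.0338, 0.29 with estimated correlation), a call that ended without KO complete-medium 72 h replicate 1 (adjusted p = 0.11). Neurod1, Aoc3 and Col8a2 were well above background in no array of 3 of the 4 groups, and Lrfn5, Ppp1r3g and Tpsg1 in none of 1, so those sizes are uncertain.

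Other splits of the same arrays were counted for every comparison. For the mean of KO against WT, 1 of 100 splits, the real one, gave as many genes (9945 against at most 4907), so assignment of the arrays by chance would rarely give this count. For differences of responses the splits were made after removing the fitted response, and the real split gave 2586 against at most 458 at 24 h, 4131 against 1685 at 72 h, 8909 against 5129 for 72 h minus 6 h in WT and 6084 against 4031 in KO cells, so 1 of 100 in each. At 6 h 4 of 100 splits reached the real 172, and the highest gave 868, several times as many, for a reason that was not tested. The splits did not keep slides or replicate numbers together. With the response kept in the data, 22, 18, 18, 8 and 10 of 100 splits were as large for these 5 comparisons, a version in which the split arrays carry the medium effect. For pairs of 3 arrays only 10 splits exist, too few for a share under 0.05. The real counts and highest others were 6269 and 493, 5808 and 2, and 7297 and 15 for KO against WT at 6, 24 and 72 h, 2694 and 4, 9766 and 1, and 12357 and 1 for the medium in WT, and 2614 and 970, 8466 and 1, and 9642 and 1805 in KO cells. The highest other split at 72 h in KO cells exchanged restricted-medium replicate 3 with complete-medium replicate 1, the arrays on slides 11 and 12.

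Genes on the chromosome of Hmox1 were higher and those on that of Top2a lower in KO cells. A few strong changes would spare most neighbours. On the first 72.6% of genes lay above and on the second 79.6% below the median of all, but picking by median largely fixed this. A copy-number difference between the lines may account for the chromosome of Top2a, where the weakest of 5 equal parts was at -0.27. It may do so for 4 parts of that of Hmox1, the weakest at 0.455. The first (0.024) speaks only against a whole-chromosome difference. The prediction covered every part, and the others were judged apart only after it failed. Whether these shifts came with the deletion of Sirt1 or with separate culture cannot be tested here, since the labels do not tell how many lines stand for each genotype.

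Meg3, Rian and Snrpn were far lower in KO cells. A variant under a single probe would spare other probes, but 4 others of Meg3 and 1 of Snrpn had a median of -5.56 (-8.65 to -2.91). Rian had no other probe to test. Loss of a chromosome would lower its other genes, but the lowest median over the chromosomes of these genes was -0.004. Loss of expression from the active parental copy may be a candidate explanation, and among 15 measured imprinted genes outside the regions of these 3, which leaves out Dlk1, Dio3 and Ndn, 14 changed, with Igf2 (2.60) and Grb10 (3.08) higher and Slc38a4 (-6.03) and Plagl1 (-1.07) lower. A change of only these regions would leave the 15 little changed, but their median absolute change was 1.07 (0.49 to 2.6, 95% bootstrap interval over genes). That spread held the bound of 1 written against this explanation, so the test could not decide. Yet 14 of 15 changed and the lower limit passed the median of all genes (0.3). This test was first left out, then put back. Methylation was not analysed here, and neither Sirt1 loss nor a line difference is excluded.

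The medium responses at 24 and 72 h were measured across slides. Were slides the source at 24 h, restricted medium at 24 h and complete medium at 72 h, on the same slides, would hardly differ over the called genes, but that difference was 0.969 of the 24 h change in WT (0.948 to 1.02 across slides) and 0.863 in KO cells (each of 2 slides at 0.865 and 0.868). At 72 h the restricted arrays lay on further slides, and the responses at 24 and 72 h correlated at 0.558 in WT and 0.485 in KO cells across genes, while a slide effect carried by the slides of 24 h restricted and 72 h complete medium would make them negative. The within-slide contrast sets 24 h against 72 h and so also holds time. A part of single changes may still come from slides.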

How the results depend on the processing

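Tests chosen only after the result was seen were those without the arrays on slides 11 and 12, with the other Sirt1 probe and without the genes of 2 chromosomes. Limits come from signal over background, since dim genes allow only bounds, and from 3 arrays per group. Quantile normalization, the median as reference, the deposited table, all probes, another variance model and the replicate block moved no count of genes by over 1.5 times. Apart from all probes, run for counts alone, they reversed no named gene or list. With normexp, KO against WT gave 3918 genes (mean), 1160, 1351 and 1896, the medium in WT 51, 3854 and 4587 and in KO 32, 2935 and 2918, the differences of responses 0, 90 and 441, and 72 h minus 6 h 1881 in WT and 1116 in KO cells. The 0 came from limma, with 297 genes at an unadjusted p under 0.05. The median residual SD was 0.502 with normexp against 0.251 otherwise. WT and KO responses then correlated at 0.4534 at 6 h and 0.8467 at 24 h. Normexp turned the sign of Slc7a11 (-0.13) in KO against WT at 6 h, of Ctxn3 (-0.31) and Rbmy (-0.07) in KO cells at 6 h and Aoc3 (0.047) at 24 h, and of Acta1 (-0.01), Slc16a4 (-0.48), Dock10 (-0.26) and B3galt1 (-0.50) in the difference at 6 h, and of the naive pluripotency list in KO cells at 6 h (adjusted p = 0.800). The cause was not tested.

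Without a filter on dim probes the difference at 6 h gave 113 genes, and the correlations were 0.2515 at 6 h and 0.6982 at 72 h. With the stricter filter they were 0.4237 at 6 h and 0.8024 at 24 h. With only the groups of a contrast, which leaves fewer degrees of freedom, KO against WT at 6 h gave 3231 genes, the medium at 6 h 1174 in WT and 1 in KO cells, the difference at 6 h 1, and 72 h minus 6 h in KO cells 3096. Slide as a random or fixed block raised the difference at 6 h to 269 and 270. Array weights, which ranged from 0.11 to 221 and whose fit stopped before it converged, gave 15390 genes for KO against WT at 72 h, 4189 for WT and 7181 for KO cells at 6 h, 16493 for KO cells at 72 h, 1134, 6013 and 10920 for the differences, and 13779 and 12703 for 72 h minus 6 h. At a fold of 1.5 or more, which takes away small changes by construction, KO against WT gave 4600 genes (mean) and 3850 (24 h), and the medium at 6 h 1537 in WT and 1467 in KO cells. The other causes were not tested. The estimated correlation left 39 list calls. Over the mean of times, Sirt1 kept its direction and its call under all settings, from -1.25 to -1.02 over single arrays left out, and the other probe gave -2.34.

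With single arrays left out the counts ranged over 9445 to 10109 (mean), 5290 to 6575, 4946 to 5284 and 6302 to 6921 for KO against WT, 2022 to 2291, 8788 to 9111 and 10524 to 12321 for the medium in WT, 1398 to 4083, 7309 to 7927 and 8329 to 9734 in KO, 101 to 332, 2128 to 2418 and 3424 to 4326 for the differences, 7767 to 9087 and 5169 to 6847 for 72 h minus 6 h, and 98 to 107 for lists. The extremes at 6 h came without KO complete-medium replicates 3 and 1 for KO cells, and without WT restricted-medium replicate 1 and KO complete-medium replicate 1 for the difference. Of 104 list calls, 19 ended without a single array. Among them were trophoblast (0.111) and serine (0.0592) lists in the 72 h difference, germline in the 24 h difference (0.0819), and 4 lists in KO cells at 6 h. Of named genes, those in KO cells at 6 h ended most often, as Asb9 (adjusted p = 0.212), Igbp1b (0.254), Lyg1 (0.116) and Shpk (0.094). The replicate number as a block gave 6325 genes for KO against WT at 6 h and 9902 for WT cells at 24 h, where the numbers pair the samples, and moved no count by over 1.5 times. It ended 2 list calls and 8 calls of named genes over all comparisons. WT and KO samples in restricted medium were paired too, and the differences of responses gave 145, 2574 and 4115. For KO against WT at 24 and 72 h in complete medium not all 3 numbers correlated, and the block gave 5787 and 7351 genes. Without the arrays on slides 11 and 12, 6 list calls ended.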

Other observations

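No test in this part was chosen only after its result was seen. In complete medium, several lists without a call as a set held strong changes in both directions between KO and WT cells. Of 12 measured trophoblast markers, 3 rose and 4 fell (3 and 4 over the list alone) (adjusted p = 0.808, 0.904 with estimated correlation), with the epithelial keratins Krt8 (2.66 ± 0.06) and Krt18 (1.48 ± 0.09) higher and Tfap2c (-1.93 ± 0.08), a transcription factor, lower. Of 18 endoderm markers, 3 rose and 9 fell (3 and 9 over the list alone) (adjusted p = 0.453, 0.674 with estimated correlation), with Sox7 (2.58 ± 0.11) higher and Foxa2 (-1.03 ± 0.11) lower. Methionine cycle genes split as well (adjusted p = 0.808, 0.862 with estimated correlation). Bhmt2 (-2.05 ± 0.08) and Bhmt (-1.45 ± 0.16), which remethylate homocysteine, fell and Adi1 (0.53 ± 0.07), of methionine salvage, rose, as 4 of 18 members rose and 6 fell (4 and 6 over the list alone). Dppa3 (-3.99 ± 0.10), a maternal factor that protects DNA methylation at imprinted loci, fell, in a naive pluripotency list that was not called (adjusted p = 0.907, 0.954 with estimated correlation). Fgf5, a primed epiblast marker, was at least 1.38-fold higher at 6 h and at least 3.16-fold higher at 72 h, and Lef1 (-1.68 ± 0.10) fell over the mean of times.

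The levels in complete medium were also set out over time. In WT cells, Mat2a lay at 6.41 ± 0.17 at 6 h and 4.33 ± 0.33 at 72 h in complete medium (SD, n = 3), and at 7.23 ± 0.12 and 6.88 ± 0.04 in restricted medium. Myc lay at 3.38 ± 0.18 and 0.40 ± 0.05 in complete and at 3.22 ± 0.21 and 2.24 ± 0.08 in restricted medium. These differences over time within a medium were not tested.

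A hypothesis was that the lower hypoxia and cholesterol lists of restricted medium at 72 h may only reflect a rise in complete medium, as cultures grow dense. In complete medium the list median per array at 72 h minus that at 6 h was 1.46 in WT and 1.06 in KO cells for hypoxia and 0.83 and 0.50 for cholesterol. In restricted medium, where that explanation needs no change, the medians were -0.70 and -0.80 for hypoxia and -0.62 and -0.69 for cholesterol, so a rise in complete medium over time would not be the whole of it. Time and slide differ together here, and cell density was not given in the sources used here.

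A further hypothesis was a genetic difference between the lines around Sirt1, which would bring changes with the deletion rather than from it. Among the 50 measured genes nearest to Sirt1, 4 (8%) changed at least 2-fold, against 9.33% of the other genes (Fisher's exact test, 2-sided, p = 1), so the neighbours showed no excess.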
